A study of Drosophila melanogaster with 6 samples.

How the data were processed

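RNA from 6 cultures of Drosophila SL2 cells was measured, 3 treated with dsRNA against Iswi and 3 with dsRNA against GST, with 1 biotin-labelled array each. Samples were grouped by the treatment in their titles. The series design calls the 3 replicates of a treatment biological, so the p-values measure the spread between separately treated cultures. The values used were the deposited log2 values per probe set. The submitters' processing notes name GCRMA, a method that in general corrects the background, normalizes between arrays by quantiles and summarises probes into probe sets. Its version, the array type, the scanner and other steps were not given in the sources used here. The values had nearly equal quantiles on every array, as GCRMA gives on a log2 scale. Such processing holds undetected transcripts at a nearly constant low level, so a fold change from that level is a lower bound at best, and it removes any global shift of RNA content between treatments.

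Of 18952 probe sets, 183 controls were left out of the tests. Of the other 18769, the platform annotation gave 1 gene symbol for 13646, several for 402 and none for 4721. Of the first of these, 13543 matched a gene table of genome Release 6, which gave current names, chromosomes and gene order, and they covered 11982 genes. No gene was named from a probe set with several symbols. A probe set was tested if it lay above a log2 value of 4 on at least 3 of the 6 arrays, which left 7390 (6465 with 1 symbol, 207 with several and 718 with none). The level of 4 was chosen, not measured. Where all arrays of 1 group were at or below it, the change is given as "at least N-fold", from the mean of the other group against the level of 4.

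Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. For gene counts and lists, the tested probe set with the highest mean over all arrays stood for its gene. Of 9 named genes with over 1 tested probe set, the probe sets of 2 (Ptp61F and RpS30) differed in sign. For Dark, H, Tl and Ptp61F the other probe set did not pass. Iswi was also tested by an exact permutation test, whose smallest p with 3 against 3 is 0.1. The 28 gene lists covered ISWI complexes, other remodelling factors, histone genes, heterochromatin, Polycomb and trithorax, dosage compensation, JAK-STAT, immune, ecdysone, heat shock, replication, mitosis, cell cycle, ribosomal, proteasome, glycolysis, apoptosis, oxidative stress, RNA interference, plasmatocyte, crystal cell and lamellocyte, neuronal, muscle, germline, Notch, homeotic, extracellular matrix and lipid genes. Lists of at least 5 tested genes were tested with camera (preset correlation 0.01, and an estimated correlation) and fry, adjusted over the lists. X-linked genes were compared with autosomal genes by camera.

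The design, the lists, the rule for named genes and most alternative settings were fixed before the data were examined. Named were Iswi, the 12 genes with the largest rise and the 12 with the largest fall among genes of 1 symbol that passed with non-overlapping groups, and from each list up to 4 passing members by smallest adjusted p. Alternatives were other filters, quantile normalization applied again, centred arrays, other variance moderation, array weights, a replicate block, other thresholds and set tests, and leaving out each array in turn. Counts per list and family under the normalizations and without each array were added after seeing the data. With arrays, the number of samples limits the precision.

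The scripts were tested on simulated data with the level and spread of each probe set in this comparison, 7390 probe sets in 20 simulations. Noise was independent between probe sets and only a small part of them was changed, unlike the data. A log2 change of 0.5, 1 and 2 was recovered in 63.1%, 92.1% and 98.6% of changed probe sets, and 4.11% of calls were unchanged probe sets. Lists of 20 genes raised by 0.3 each, with no other gene changed, had an unadjusted camera p under 0.05 in 100% of simulations, and unchanged lists in 0%. This does not show how often camera would find a change in the real lists, whose genes are correlated and whose p-values were adjusted.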

Results

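Total RNA from Drosophila SL2 cells, a line derived from late embryos with features of haemocytes (insect blood cells), was hybridised to single-colour oligonucleotide arrays. Iswi encodes the ATPase shared by several nucleosome remodelling complexes. Cells were treated for RNA interference with 10 micrograms of double-stranded RNA (dsRNA) against Iswi or against GST, the control target, for 1 hour in serum-free medium, and were harvested after 7 days. Each treatment had 3 biological replicates and 1 array per replicate, and the question was which transcripts changed when Iswi was depleted. On the deposited log2 scale, 7331 to 7334 probe sets of each GST array and 7364 to 7416 of each ISWI array lay above a value of 4. Pearson correlations across all probe sets, which are not independent replicates, were 0.9994 to 0.9996 within the GST group, 0.9983 to 0.9988 within the ISWI group and 0.9937 to 0.9959 between groups. The median SD per probe set was 0.11 in the ISWI group and 0.07 in the GST group.

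Signs of RNA quality differed between single arrays. The 3' minus 5' difference of the eIF-4a control probe sets was 2.26 on ISWI replicate 2 and 1.69 to 1.91 on the other arrays, and that of actin was 1.06 on this array and 0.40 to 0.55 elsewhere. The 18S rRNA probe sets averaged 12.99 on GST replicate 1 and 8.31 to 9.30 on the others. These values are given as measured. Counts without single arrays stand beside some gene groups, among them those whose total moved by over 1.5 times. Other counts moved too. Leaving out 1 array gave 9 to 16 higher and 6 to 7 lower oxidative stress genes, and 3 to 4 higher and 5 to 8 lower mitosis genes. For X-linked genes it gave 150 to 224 higher and 108 to 179 lower.

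The Iswi transcript itself was lowered. Its probe set fell from 10.51 ± 0.03 in the GST group to 7.52 ± 0.31 in the ISWI group (mean ± SD of log2 values, n = 3 each), a log2 fold change of -2.99 with a standard error of 0.14 and a limma adjusted p = 7.61e-06. The ISWI group thus held 12.6% of the GST level. All 3 ISWI arrays lay below all 3 GST arrays, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. The labels do not give the position of the dsRNA, and a probe set inside its target could also detect residual dsRNA.

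Genes for several enzymes were among the largest rises after Iswi dsRNA. The genes Ance-5 and Acer, related to angiotensin-converting enzyme, rose by a log2 fold change of 5.22 (standard error 0.25) and 4.63 (standard error 0.08). Ance-5 had a GST mean of 4.05, near the level of 4, so the size of its rise is a lower bound at best. Acer went from 6.18 ± 0.12 to 10.80 ± 0.04 (SD, n = 3). The cytochrome P450 gene Cyp6d5 rose by 3.75, ringer, which encodes a microtubule-associated protein, by 3.73, and the glutathione S-transferase gene GstD7 by 3.66, with limma adjusted p = 4.23e-06, 4.36e-06 and 0.000129. No untreated cells were measured. A higher value of a glutathione S-transferase gene against GST dsRNA could thus also be a fall in the control cells, which was not tested. Of genes known only by number, CG42675, CG33225, CG14787, CG33465, CG42807, CG9008 and CG8399 were at or below 4 on all GST arrays. Their rises were bounded at at least 23.8-fold, 13-fold, 8.79-fold, 7.80-fold, 5.35-fold, 11.6-fold and 4.64-fold.

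The largest falls were led by CtsL4, a cathepsin L-like protease gene, which dropped to or below 4 on every ISWI array and was at least 10.4-fold lower. Agpat2, encoding an acyltransferase of phospholipid synthesis, fell from 7.26 ± 0.09 to 3.96 ± 0.16 (SD, n = 3). Its ISWI mean lay near the level of 4, so the size of this fall is a lower bound at best. The cap-binding translation factor gene eIF4E6 fell by 3.16. The cell adhesion gene Nrg (Neuroglian) fell by 2.79 on the probe set with the higher signal, and the other gave -3.14. The glycosyltransferase gene Ugt37D1 and the nuclear export factor gene Nxf3 fell, with log2 fold changes of -2.46 and -2.45, and piwi, an Argonaute gene of the piRNA pathway, fell by 2.26. CG4210 and CG10581 fell, at -2.56 and -2.28, and CG4872 and CG3457 were at least 3.23-fold and 1.49-fold lower. Limma adjusted p for these genes ran from 1.06e-06 for CtsL4 to 0.000598 for Nxf3, with 3 of 3 ISWI arrays on the stated side of all GST arrays.

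**Figure D1:**
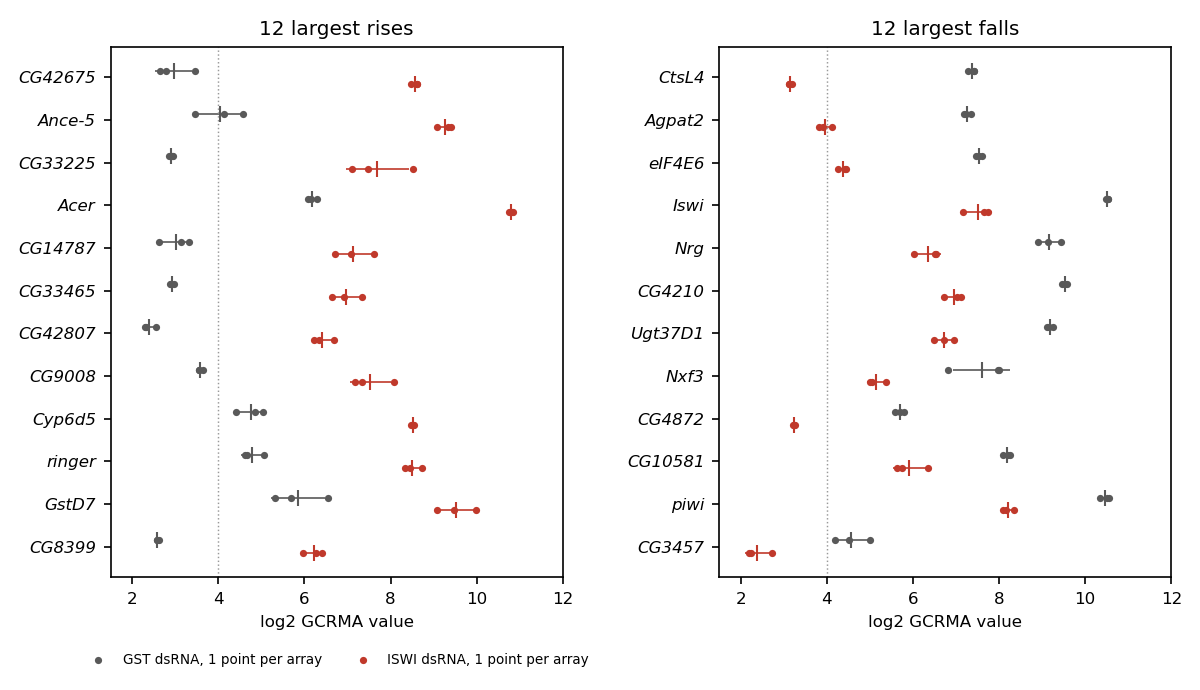
Deposited log2 values of the 12 genes that rose most and the 12 that fell most, 1 point per array, with the group mean (vertical tick) and SD (line). The dotted line marks the level of 4; Acer lay at 6.18 ± 0.12 in the GST group and 10.80 ± 0.04 in the ISWI group, and Iswi at 10.51 ± 0.03 and 7.52 ± 0.31.

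Of 7390 tested probe sets, 2974 (40.2%) passed limma's adjusted p of 0.05, of which 1634 were higher and 1340 lower in the ISWI group. This balance turned under other scaling, to 1476 higher and 1510 lower with centred arrays and 1513 and 1522 when quantile normalization was applied again. Most differences were small: 908 probe sets changed at least 1.5-fold (518 higher, 390 lower), 367 at least 2-fold (247 higher, 120 lower) and 95 at least 4-fold (76 higher, 19 lower). Counted as genes, 2468 of 6011 (41.1%) passed, 1408 higher and 1060 lower. A gene list with a share near this one does not stand out from all genes. The 247 probe sets higher by at least 2-fold had a median GST level of 5.65, and 48 of them were at or below 4 on all GST arrays. The 120 lower by at least 2-fold had a median GST level of 8.33, and 11 were at or below 4 on all ISWI arrays. The groups did not overlap for 3997 probe sets (54.1%), against 10% by chance for 3 against 3. The number of arrays limits the precision, and calls of under 1.5-fold rest on the small spread between replicates.

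**Figure D2:**
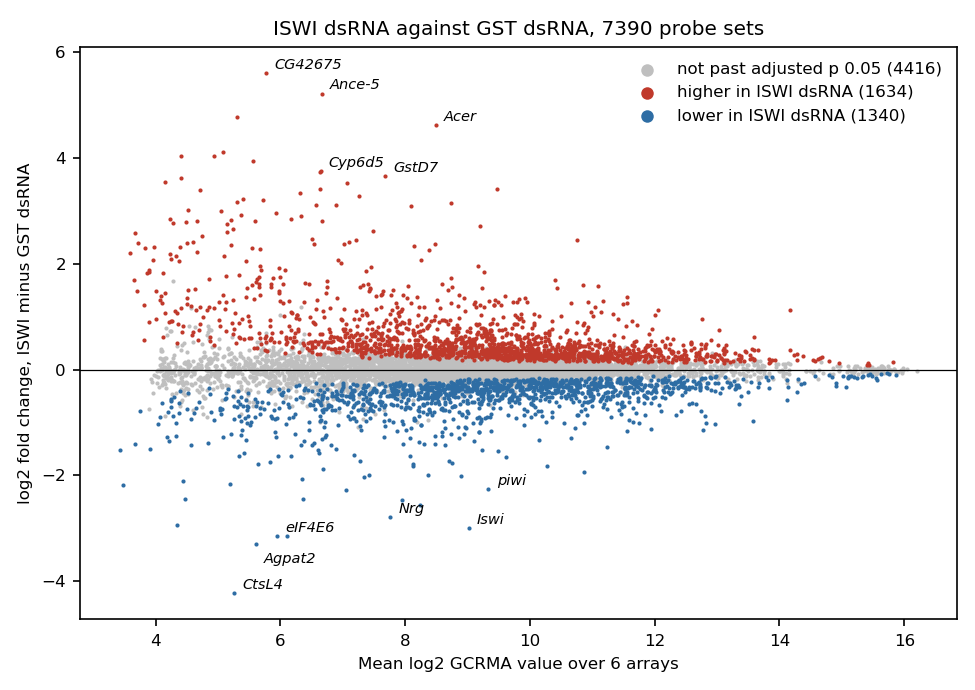
Log2 fold change (ISWI minus GST dsRNA) against the mean log2 value over 6 arrays for 7390 probe sets, coloured by the limma result. Among the 1634 higher probe sets CG42675 was at least 23.8-fold higher, and among the 1340 lower ones CtsL4 was at least 10.4-fold lower; where a group lies at or below 4 the plotted change is no measured size.

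Within the RNA interference machinery, 7 of 20 genes fell and 1 rose. The Argonaute genes piwi and aub, which act with piRNAs in the germline, fell, with log2 fold changes of -2.26 and -1.65, and AGO3, of the same family, fell from 8.41 ± 0.19 to 6.42 ± 0.33 (SD, n = 3). The gene blanks, which encodes a dsRNA-binding protein, fell by 1.14. Limma adjusted p for these ran from 3.78e-06 for blanks to 0.00011 for AGO3. Adjusted over the list alone, 1 was higher and 8 were lower. The list as a set did not pass camera (adjusted p = 0.0715, and adjusted p = 0.743 with an estimated correlation). Without GST replicate 2 and without ISWI replicate 3 its adjusted p was 0.0476 and 0.0441, over a range of 0.00281 (by fry) to 0.743 across settings.

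Genes of lipid and sterol metabolism were mostly lower where they changed, with 8 of 18 falling and 1 rising. The log2 fold change was -0.73 for the phosphocholine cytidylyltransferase gene Pcyt1, -0.71 for acetyl-CoA carboxylase (ACC), -0.31 for fatty acid synthase (FASN1) and -0.93 for the lipid droplet gene Lsd-1. The count adjusted over the list alone was 1 higher and 9 lower, with camera adjusted p = 0.0715 and adjusted p = 0.743 with an estimated correlation. Without GST replicate 2 and without ISWI replicate 3 the adjusted p was 0.0476 and 0.0328, over a range of 0.00685 (by fry) to 0.743 across settings. Without ISWI replicate 1 the count was 2 higher and 8 lower. Of 27 proteasome subunits 14 rose and 2 fell. Prosbeta3, Prosbeta6 and Prosbeta7 rose by 0.34, 0.33 and 0.31, and Prosalpha6 fell by 0.35, with 10 higher and 1 lower without GST replicate 1 and without GST replicate 2. The proteasome count adjusted over the list alone was the same (14 and 2), with camera adjusted p = 0.144 and adjusted p = 0.743 with an estimated correlation.

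Among other chromatin factors, 8 of 22 remodelling ATPases and partners fell and 2 rose. The annealing helicase gene Marcal1 (-1.05), Chd1 (-0.61) and mor (-0.24) fell, and MTA1-like rose by 0.40. Without ISWI replicate 1 the count was 4 higher and 9 lower, without each of the GST arrays it was 1 and 7, and without ISWI replicate 2 it was 1 and 8. Of 15 Polycomb and trithorax group genes 4 fell (Psc at -0.60, Utx at -0.40, Pcl at -0.30 and Sce at -0.26) and 0 rose, and 2 fell without GST replicate 2 and without GST replicate 3. Counts adjusted over the list alone were the same for both lists, and both had camera adjusted p = 0.171 and adjusted p = 0.743 with an estimated correlation. Of 10 histone-related genes 2 rose and 2 fell, led by the histone chaperone gene Nap1 (-1.02) and yem (-0.41), with Slbp at 0.31 and asf1 at 0.32, and the count was 0 higher and 2 lower without GST replicate 2 and 1 and 2 without any other array but ISWI replicate 1. Of 18 heterochromatin proteins 2 rose, su(Hw) by 0.79 and HP4 by 0.31, and HP1b fell by 0.26, and without ISWI replicate 1 the count was 4 higher and 2 lower. Both counts were the same adjusted over the list alone. Neither list reached the share of 41.1% that passed among all tested genes. Camera gave adjusted p = 0.484 for the histone list and 0.655 for heterochromatin, and adjusted p = 0.790 and 0.853 with an estimated correlation. Of 4 tested subunits of ISWI complexes, Iswi fell and Caf1-55 was higher by 0.13, a call lost when the arrays were centred and when any array was left out, and the list was too small for a set test. The count for these subunits adjusted over the list alone was 1 higher and 1 lower.

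Of 11 crystal cell and lamellocyte markers, genes of specialised insect blood cells, 5 rose and 1 fell. The prophenoloxidase genes PPO1, PPO2 and PPO3, whose products act in melanisation, rose by 1.54, 0.76 and 0.66, and the tubulin gene betaTub60D rose by 1.35. The count adjusted over the list alone was the same, with camera adjusted p = 0.171 and adjusted p = 0.743 with an estimated correlation. Without the filter on dim probe sets the list passed at adjusted p = 0.0218, over a range of 0.00583 (by fry) to 0.743 across settings. Markers of plasmatocytes, the phagocytic blood cells that SL2 cells resemble, went both ways, with 7 of 29 higher and 6 lower. Itgbn, eater and drpr, which encode phagocytosis receptors, rose by 1.19, 0.75 and 0.51, and NimC1, another such receptor gene, fell by 0.86. The plasmatocyte count was the same adjusted over the list alone, with camera adjusted p = 0.920 and adjusted p = 0.965 with an estimated correlation. Without GST replicate 1 and without GST replicate 2 the count was 6 higher and 2 lower, and without GST replicate 3 it was 5 and 1, while without ISWI replicate 1 it was 7 higher and 10 lower.

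Of 13 antimicrobial and immune genes 5 rose and 2 fell. The antimicrobial peptide genes Mtk and Drs rose, Mtk by at least 5.45-fold from a GST level at or below 4 and Drs by a log2 fold change of 1.92. The recognition protein gene GNBP3 rose by 0.53 and the receptor gene Tl fell by 0.49. The other Tl probe set gave -0.23 and did not pass. The count adjusted over the list alone was the same, with camera adjusted p = 0.456 and adjusted p = 0.743 with an estimated correlation. In the JAK-STAT list 5 of 11 genes rose and 1 fell. The transcription factor gene Stat92E fell by 0.45, and Socs44A, vir-1 and Ptp61F rose by 0.39, 0.34 and 0.32, with a value of -0.09 on the other Ptp61F probe set, which did not pass. Without GST replicate 2 the count was 3 higher and 1 lower, and without GST replicate 3 it was 2 and 1. It was 5 and 1 adjusted over the list alone, with camera adjusted p = 0.645 and adjusted p = 0.791 with an estimated correlation.

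Of 33 oxidative stress and detoxification genes 12 rose and 7 fell, so that members of one enzyme family moved in opposite directions. The glutathione S-transferase genes GstE13 and GstO1 fell, at -2.02 and -1.41, and GstD3 and the peroxiredoxin gene Prx6c rose by 0.95 and 0.96. For the glutathione S-transferase genes, a change in the control cells given GST dsRNA was not tested, as no untreated cells were measured. Adjusted over the list alone 15 rose and 7 fell, with camera adjusted p = 0.449 and adjusted p = 0.853 with an estimated correlation. Of 11 heat shock genes 3 rose (Hsp27 by 1.27, the co-chaperone gene stv by 0.95 and Hsp68 by 0.74) and 2 fell, among them Hsc70-5 (-0.30), with 1 lower without GST replicate 2, GST replicate 3, ISWI replicate 1 or ISWI replicate 2. The count adjusted over the list alone was the same, with camera adjusted p = 0.787 and adjusted p = 0.915 with an estimated correlation. Of 20 apoptosis and DNA damage genes 3 were higher and 2 lower. This became 2 and 3 when the arrays were centred or quantile-normalized again, and also without ISWI replicate 2. Dark and Dcp-1, of the caspase pathway, rose by 1.01 and 0.67, and the caspase gene Dronc and PolZ1, for a DNA polymerase, fell, at -0.33 and -0.36. The other Dark probe set gave 0.43 and did not pass. The share of apoptosis and DNA damage genes that passed lay below the 41.1% of all tested genes. Adjusted over the list alone 2 were higher and 2 lower, with camera adjusted p = 0.967 and adjusted p = 0.966 with an estimated correlation.

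Of 27 mitosis genes 6 fell and 3 rose. The anaphase activator gene fzy (-0.91), feo (-0.65) and Bub3 (-0.28) fell, and pim, which encodes securin, rose by 0.48. Of 17 cell cycle regulators 2 were lower (mip130 at -0.40 and Cdk4 at -0.30) and 0 higher, with 0 lower without GST replicate 2 and 1 lower without GST replicate 1, GST replicate 3 or ISWI replicate 3. Of 34 DNA replication genes 7 rose and 2 fell, led by dpa (-0.45), PolA2 (-0.40), Orc5 (0.37) and RPA3 (0.36), and 3 rose and 2 fell without GST replicate 2 and without GST replicate 3, against 4 and 2 without GST replicate 1. Of all 6011 tested genes 41.1% passed, a share that none of these lists reached. Adjusted over the list alone the counts were 3 higher and 6 lower, 0 and 1, and 4 and 2. Camera gave adjusted p = 0.390 for mitosis and cell cycle and 0.655 for replication, and adjusted p = 0.743, 0.743 and 0.866 with an estimated correlation.

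Extracellular matrix and adhesion genes were lower in 6 of 18 cases and higher in 1. Nrg (-2.79), the integrin gene mew (-0.54) and the laminin gene LanB1 (-0.38) fell, and the integrin gene Itgbn rose by 1.19. The count adjusted over the list alone was the same, with camera adjusted p = 0.171 and adjusted p = 0.743 with an estimated correlation. Without GST replicate 2 the count was 1 higher and 3 lower, without GST replicate 3 it was 1 and 2, and without ISWI replicate 2 it was 2 and 5. Of 8 neuronal genes 5 were higher and 2 lower, and Nrg belongs to both lists. The number of lower neuronal genes was 3 without ISWI replicate 1 and 1 without any other array. Snap25, which encodes a protein of synaptic vesicle release, was at least 2.65-fold higher than a GST level at or below 4, and unc-13 and Dscam1 rose by 0.73 and 0.70. The neuronal count adjusted over the list alone was 5 higher and 3 lower, with camera adjusted p = 0.484 and adjusted p = 0.743 with an estimated correlation. Of 5 muscle genes bt fell by 0.51 and 0 rose, 2 fell without ISWI replicate 2, and camera gave adjusted p = 0.484 and adjusted p = 0.757 with an estimated correlation. The muscle count adjusted over the list alone was 0 higher and 1 lower.

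Among developmental genes, fng, a Notch-modifying glycosyltransferase gene, was at least 5.76-fold higher than a GST level at or below 4. E(spl)m3-HLH and neur, also of the Notch list, rose by 0.70 and 0.53, and the antagonist gene H fell by 0.51, which made 3 of 8 genes higher and 1 lower. The other H probe set gave -0.15 and did not pass. Without GST replicate 1 the count was 3 and 0, without GST replicate 2 it was 2 and 0, and without GST replicate 3 it was 2 and 2. Of 4 homeotic and segmentation genes cad was at least 1.98-fold higher, and hry and tsh were lower at -0.32 and -0.27, with no set test for a list this small and 1 lower without any GST array or ISWI replicate 3. Of 16 ecdysone response genes 3 rose and 3 fell, with Cth, for an enzyme of cysteine synthesis, at -1.11, Hnf4 at -0.44, Sox14 at 0.42 and Eip63E at 0.32. Of 7 germline and testis genes 3 were higher (gcl by 0.59, stau by 0.44 and mia by 0.25) and Sxl fell by 0.69. The germline count was 1 higher and 1 lower without GST replicate 1, GST replicate 2, ISWI replicate 1 or ISWI replicate 2. Counts adjusted over the list alone were the same for the Notch, homeotic, ecdysone and germline lists. Camera gave adjusted p = 0.655 for the Notch and germline lists and 0.645 for ecdysone, and adjusted p = 0.853, 0.866 and 0.853 with an estimated correlation.

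Of 35 genes matched to the list of cytosolic ribosomal proteins 4 were higher and 6 lower, with RpLP0 at 0.08, RpS30 at -0.10 and RpLP2 at -0.12. Among the 4 was qm (0.56), which encodes a geranylgeranyl diphosphate synthase and had entered the list through a former name of RpL10. Without qm, 3 of 34 were higher and 6 lower, and 0 and 0 adjusted over the list alone, with camera adjusted p = 0.351 and adjusted p = 0.808 with an estimated correlation. These 34 still held genes whose symbols end in -like. Without them as well, 3 of 31 were higher and 5 lower, with the same camera values. The other RpS30 probe set, of low signal, rose by 2.41. With qm, leaving out 1 array gave 1 to 2 higher and 2 to 5 lower ribosomal genes. That total moved by over 1.5 times without any array but ISWI replicate 3, and adjusted over the list alone 1 was higher and 2 lower. Quantile normalization applied again turned the ribosomal median from -0.0174 to 0.00429, with 4 higher and 4 lower. Of 11 glycolysis enzymes Eno and Tpi fell, at -0.33 and -0.43, and Pfk rose by 0.35, the same adjusted over the list alone, and the count was 2 higher and 3 lower without ISWI replicate 3 and 2 and 2 without GST replicate 1 or ISWI replicate 1. Camera gave adjusted p = 0.456 for ribosomal proteins and 0.920 for glycolysis, and adjusted p = 0.853 and 0.965 with an estimated correlation.

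Over the 26 lists of at least 5 tested genes, 0 passed camera's adjusted p of 0.05 and 7 had an unadjusted p under 0.05. With an estimated correlation 0 passed and 0 had an unadjusted p under 0.05. Camera compares a list with the other genes, whereas fry asks if a list's genes move, on balance, in 1 direction without comparing them with other genes. By fry, 14 lists passed an adjusted p of 0.05. The signs of median, mean and camera direction differed for heat shock (median -0.01, mean 0.23, camera up), glycolysis (median 0.04, mean 0.02, camera down), plasmatocyte markers (median -0.08, mean 0.04, camera down), dosage compensation (median -0.02, mean 0.04, camera down) and the ribosomal list (median -0.02, mean 0.00394, camera down, and a mean of -0.0126 without qm). For the homeotic list, which had no set test, the median was -0.13 and the mean 0.43. The heat shock median turned to 0.01 when quantile normalization was applied again and lay between 0.01 and 0.04 without any array but GST replicate 1. The dosage compensation median was 0.01 without GST replicate 1 and 0.02 without ISWI replicate 1, and the plasmatocyte median ran from -0.13 without ISWI replicate 1 to -0.01 without ISWI replicate 3.

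**Figure D3:**
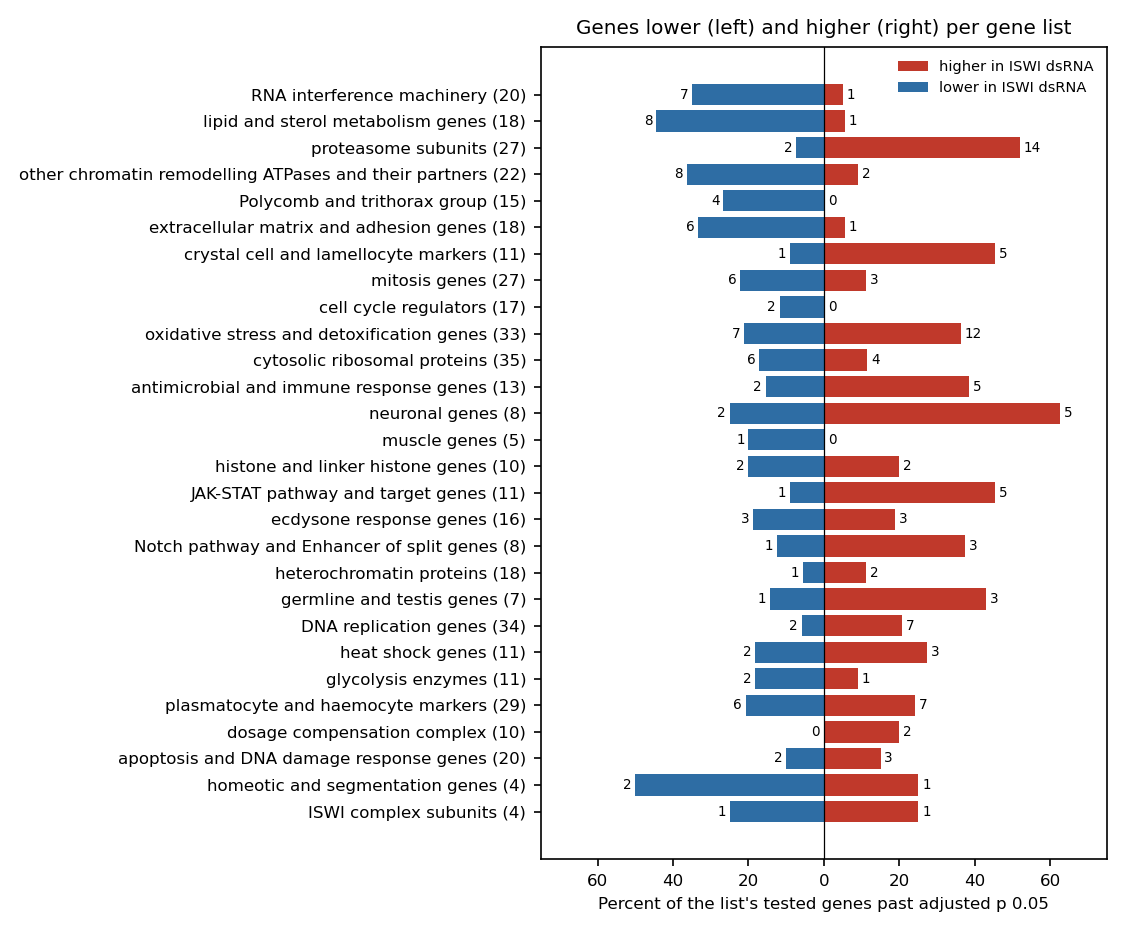
Percent of each list's tested genes (number in brackets) that were lower (left, blue) or higher (right, red) at a limma adjusted p of 0.05, with the number of genes beside each bar. Proteasome subunits had 14 higher and 2 lower, and the RNA interference machinery 1 and 7. Of all 6011 tested genes, 1408 were higher and 1060 lower. The apoptosis list turned from 3 higher and 2 lower to 2 and 3 when the arrays were centred or quantile-normalized again, and also without ISWI replicate 2.

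SL2 cells are a male line in which the dosage compensation complex raises transcription of X-linked genes, so these genes were compared with autosomal ones. The 1022 X-linked genes had a median log2 fold change of 0.02 and the 4933 genes on 2L, 2R, 3L and 3R a median of 0.03, a difference of -0.02 that did not pass camera (p = 0.601, and p = 0.780 with an estimated correlation). On the X chromosome 215 genes were higher and 166 lower, and 196 were higher and 203 lower, with a median of -0.02, when quantile normalization was applied again. Of 10 tested genes of the dosage compensation list, msl-2 rose by 0.32 and JIL-1 was higher by 0.29, and 0 were lower. The count was 1 higher without each array in turn, when the arrays were centred and adjusted over the list alone. Camera gave adjusted p = 0.967 for this list and adjusted p = 0.966 with an estimated correlation.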

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

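The test of the control probe sets was chosen only after the array values were seen. Control probe sets lie outside the comparisons above, and 1 of their measures was higher on every ISWI array than on every GST array. The 3' minus 5' difference for the eIF-4a controls, a sign of RNA integrity or labelling, was 1.76 ± 0.08 in the GST group and 2.01 ± 0.22 in the ISWI group (log2, SD, n = 3 each), a difference of 0.246 with an exact permutation p of 0.1, the smallest possible (0.4 adjusted over the 6 measures). ISWI replicate 2 had 2.26. The same difference for actin (0.226, exact p = 0.2) and GAPDH (0.0868, exact p = 0.7) did not separate the groups. The poly-A spike-in controls differed by 0.298 (exact p = 0.4) the hybridization controls by -0.312 (exact p = 0.2) and the 18S rRNA probe sets by -1.33 (exact p = 0.7).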

How the results depend on the processing

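The counts per list, family and chromosome without each array and under other normalizations were chosen only after the data were seen. So was the ribosomal list without qm and without -like genes. All other settings were planned. No named result changed direction past its threshold, but the balance of calls turned with other scaling (see the counts above). The 2974 probe sets became 908 at 1.5-fold (518 higher, 390 lower), 367 at 2-fold (247 and 120) and 1749 at an adjusted p of 0.01 (986 and 763), as stricter thresholds require. Other settings gave 2236 (no filter) to 3035. Leaving out 1 array gave 2100 to 3023 (1188 to 1706 higher, 912 to 1317 lower). Iswi stayed between -3.10 and -2.81 without 1 array. The 0 lists past camera became 14 by fry, which asks a different question, 1 without the filter (crystal cell and lamellocyte markers) and 0 to 2 without 1 array. The 2 were RNA interference and lipid metabolism, both without GST replicate 2 and without ISWI replicate 3. The causes were not tested. The X minus autosome difference did not pass in any setting.

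Same-number correlations between GST and ISWI arrays ran from -0.18 to 0.12, and 1 of 6 arrays correlated best with its own number. Different-number correlations ran from -0.24 to 0.14, so the values showed no clear pairing by replicate number. Correlations between so few arrays cannot decide if arrays of the same number shared a batch, and the labels do not say. With a replicate block 2808 probe sets passed (1528 higher, 1280 lower), 2684 of them among the 2974, and 0 lists.

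Of the named genes, Caf1-55, JIL-1 and mia lost their call in 13 settings each, RpLP0 in 9, asf1 and tsh in 7, Cdk4 in 6 and stau in 5. Centring the arrays moved the share of higher calls from 54.9% to 49.4%. Changes near the level of 4 are limited by signal over background.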

Other observations

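The tests of gene families, chromosome 4, neighbouring genes and rises against falls were chosen only after the changes were seen, and the intervals that decide them were added after their first values were known. Of 79 groups of at least 5 genes that share a symbol stem, 6 passed camera's adjusted p of 0.05 with the preset correlation and 0 with an estimated one (adjusted p = 0.987 with an estimated correlation for each). Of 8 CCT genes, for subunits of the cytosolic chaperonin that folds actin and tubulin, 7 fell and 0 rose (median -0.34, camera adjusted p = 0.00102). Of 16 PIG genes, which act in synthesis of the GPI anchor of surface proteins, 12 rose and 0 fell (median 0.43, camera adjusted p = 0.00102), and 7 rose without GST replicate 1.

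Of 25 genes for subunits of mitochondrial complex I (ND symbols) 15 rose and 0 fell (median 0.19, camera adjusted p = 0.00102), and 6 of 7 cytochrome c oxidase (COX) genes rose and 0 fell (median 0.27, camera adjusted p = 0.0211). With an estimated correlation the unadjusted p was 0.166 and 0.118. Of 6 mthl genes, which encode receptors related to methuselah, 5 rose (median 0.89, camera adjusted p = 0.0412), and of 6 Arpc genes, for subunits of the actin-nucleating Arp2/3 complex, 4 fell (median -0.24, camera adjusted p = 0.0445). These directions held when the arrays were centred or quantile-normalized again.

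Of 42 genes on chromosome 4, a small chromosome rich in heterochromatin, 16 fell and 4 rose. Their median was -0.13 (bootstrap interval over genes -0.396 to 0.000879, which reaches 0) against 0.03 on the other chromosomes (camera p = 0.000661, and p = 0.121 with an estimated correlation). The bootstrap intervals take genes as independent units and do not measure the spread between cultures. Sox102F, CG1674 and CG32017, named after their values were seen, fell, at -1.64, -1.41 and -1.34. Only 0.19% of 10000 level-matched random lists had a median as low, which argues against expression level, and without ISWI replicate 2 the median was -0.118 (-0.363 to -0.0374) and the same genes moved by a median of -0.0191 (-0.0336 to 0.0155), which argues against the 3' bias of that array. Without the 5 largest falls the median was -0.0815 (-0.190 to 0.0380). Leaving out only falls can never lower a median, so this value does not decide if a few genes account for it, which stays open. The median of all 42 genes also shrank without GST replicate 2 (-0.0807) and without ISWI replicate 3 (-0.0746). An effect of Iswi depletion on this chromosome stays open as an untested hypothesis.

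In the order of tested genes along each chromosome, genes raised at least 2-fold followed each other more often than level-matched permutations gave. There were 16 pairs against 7.90, a ratio of 2.03. Only 0.69% of 10000 permutations had as many, which argues against level. Untested genes were skipped and no limit of distance was set, so the genes of a pair need not be direct neighbours on the chromosome. Runs included Cyp6a22, Cyp6a17 and Cyp6a23, raised by 1.54, 1.69 and 1.62, and nvy with betaTub60D at 3.42 and 1.35. Leaving out the probe set types that match several transcripts also left fewer genes in the order, which made new pairs possible. The ratio was then 2.12 (Poisson interval 1.16 to 3.57, permutation p = 0.0045), which argues against those types as the whole cause. A part of the ratio could still come from cross-hybridisation, since the interval holds 1.5 and the Cyp6a genes are paralogs. Genes lowered at least 2-fold gave 5 pairs against 1.60 (p = 0.022 by permutation).

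Of probe sets changed at least 2-fold, 67.3% rose (exact interval 62.2% to 72.1%). The intervals of this share take probe sets as independent units, though all come from the same 6 arrays. They do not measure the spread between cultures and may be too narrow. The share was 64.2% with centred arrays and 66.5% without ISWI replicate 2, both with intervals above 55%. Centring moves only what the deposited normalization left, since the tested medians already lay at 9.03 to 9.09. It therefore does not decide about that normalization. The share without ISWI replicate 2 argues against the 3' bias of that array as the whole cause. Among probe sets with a mean over 6 in both groups, a filter that treats the groups alike, the share of rises was 60.1% (52.6% to 67.3%). Since this interval holds 55%, a low level of the genes stays open. A split by the GST mean gave 52.1% over 6 and 87.8% at 6 or under, but it decides nothing, because the GST mean is a side of the change and probe sets dim on all GST arrays were tested only if bright on all ISWI arrays.

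The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2974 probe sets and the highest other 0, so that 1 of the 10 reached the real count. Every other split mixes GST and ISWI arrays, so a treatment difference adds to its spread and lowers its count. The contrast of 2974 with 0 therefore does not measure how many calls arise by chance. For gene lists the real split gave 0 and the highest other 4; a count of 0 is reached by any split, here 10 of 10, so this comparison says nothing. For the X chromosome the real p was 0.601 and the smallest other 0.214, with 7 splits as small.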
